A study of Saccharomyces cerevisiae with 72 samples.

How the data were processed

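The series holds 72 Agilent arrays with a pair of colours, each carrying one yeast strain of the BY4741 background treated with methyl methanesulfonate (MMS, a DNA alkylating agent) in one channel and the same strain untreated in the other. Per the labels, treatment lasted 1 h. Per the labels, 52 arrays of 13 strains were made from poly(A)-enriched RNA; they are called the kinase set here. The other 20 arrays, of 5 strains lacking a transcription factor, were made from total RNA, stand in a separate table on another array design and hold no wild type; they are called the factor set. For the kinase set the growth text gives 0.03% MMS and the treatment text 0.033%. For the factor set both give 0.03%.

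The authors deposited 1 normalized log ratio per probe and array, taken here as log2 of Cy5 over Cy3. Per the submitters' processing notes the arrays were normalized with limma, without a version; base 2 is assumed because limma works in log2, and neither the base nor the centring is stated. The direction comes from the dyes and titles in the labels: values of arrays with MMS in Cy3 were multiplied by -1, so that each value is log2 of MMS over untreated. The arrays had not been turned before deposit, since arrays of one strain with opposite dyes correlated negatively over probes as deposited, with r from -0.876 to -0.174 in the kinase set and from -0.847 to -0.633 in the factor set. Array medians lay between -0.018 and 0.021 in the kinase set and between -0.012 and 0.0094 in the factor set. No value was missing.

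Of 6269 probes in the kinase table, 5620 were paired with 1 gene symbol, 0 with several and 649 with none, which left 5594 genes. The factor table had 6256 probes, 5609 with 1 symbol, 0 with several and 647 without, and 5592 genes, 1 of them with an Entrez identifier that had no match in the reference. Probes of one gene were averaged. This affected 25 genes and 16 genes, and in the wild-type response the probes of RSO55 differed by 1.20. Probes without a symbol entered no test on genes.

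The unit of replication was the replicate number of the titles. The 2 arrays of a strain that share a number have opposite dyes and were averaged, which cancels a constant dye effect and gives n = 2 per strain. The labels do not say whether arrays with the same number share RNA extracts or whether the replicates are separate cultures, so p-values measure the spread among these samples. Errors are the SD of 2 replicates or the standard error (SE) of the fit.

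One mean per strain was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with statmod 1.5.0, apart for each table. The fits had 13 and 5 residual degrees of freedom, with 6.57 and 4.80 prior degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, adjusted per contrast over all genes, and the number of called genes that changed at least 2-fold is given beside the counts. The contrasts were the response of each strain against 0, each of 12 deletion strains minus wild type, the 4 double deletions each minus a single one, mec1 minus rad53, and in the factor set each strain minus the mean of the other four. No test crosses the 2 tables. A deleted gene's ratio compares treated with untreated cells of the same strain, so a value near 0 does not check the deletion, while a value far from 0 that does not go with the dye goes against the label of a channel. The place of the probes within the deleted genes is not given. The labels do not say whether the mec1 and rad53 strains also lack SML1.

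The 25 gene lists, the fits, the rule for naming genes and all alternatives but those named below as added were set before the data were examined. A gene is named if it was called and all its arrays had one sign (responses) or its replicates in one strain all lay beyond those in the other (differences), ranked by the size of the log2 value. The 10 highest and 10 lowest are named for the wild-type response and for mec1, rad53, dun1, crt1 and tel1mec1 against wild type, and the 3 highest and 3 lowest elsewhere. Members of the lists and the deleted genes may be named as well. HIS3, LEU2, MET17 and URA3, which BY4741 lacks, were left out of the lists. Some members of the lists were not analysed here.

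Lists were tested with limma's camera at a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it, with Benjamini-Hochberg adjustment over all lists and contrasts of a family. In the responses of the kinase set, 211 of 325 list tests passed with the preset correlation, 38 with the estimated one and 249 with fry; for the differences from wild type the numbers were 115, 13 and 57 of 300, and for the direct contrasts 41, 7 and 12 of 125. In the factor set they were 77, 0 and 105 of 125 for the responses and 43, 0 and 11 of 125 for the differences. Members were also counted after adjustment over the list alone.

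The share of the wild-type response kept by a strain is the slope through 0 of its log2 ratios on one wild-type replicate, divided by the same slope of the other wild-type replicate. It was taken over genes with an absolute log2 ratio of at least 1 in that replicate (282 and 320 genes) and averaged over both choices of replicate, with no test.

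The alternatives were the arrays as samples with the dye-swap pair or the slide as a random block (duplicateCorrelation), the replicate number as a block, centring each array on its median, scaling the arrays to one median absolute value, the 75% of genes with the larger spread, the median of probes, leaving out each replicate in turn (for differences, of the deletion strain), sml1 as the reference, the other list tests, and an absolute log2 ratio of at least 2 for the share kept. A dye term, leaving out a wild type replicate in the differences, leaving out the 3 pairs with the strongest dye effect, leaving out 3 single arrays that stand apart or the 1 of them whose deleted gene goes against its label (so that a replicate is 1 array and its dye effect does not cancel), and the share kept for risen and fallen genes apart were chosen after seeing the data. Slides were known for the kinase set only: 18 slides held 1 to 4 arrays each, and 7 of them held several strains.

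The fits were tested on simulated data with the real genes and 200 changed genes per contrast. The noise was normal with each gene's residual spread, independent between genes and replicates, and without dye, slide or single-array effects. In the responses fewer genes were changed than limma called in the data. The shares below hold for such data only, and recovery in the real data may be lower. For the wild-type response, 86.6% of genes changed by a log2 of 0.5 were recovered, and 100% of those changed by 1 or by 2, with 11 false calls. For rad53 minus wild type, 52.2% were recovered at 0.5, 98.5% at 1 and 98.5% at 2, with 3 false calls. For tel1mec1 minus mec1 the shares were 62.7%, 94.0% and 98.5%, with 11 false calls. In the factor set, 89.6% were recovered at 0.5 for the hap1 response and 82.1% for hap1 minus the other four, with 9 and 13 false calls.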

Results

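Messenger RNA was compared between yeast cells exposed to MMS for 1 h and untreated cells of the same strain. MMS methylates DNA and stalls replication, and the damage is signalled through the kinases Mec1 and Tel1 to Rad53 and Chk1, and from Rad53 to Dun1. The kinase set holds 13 strains: wild type, the single deletions sml1, mec1, tel1, rad53, chk1 and dun1, the double deletions tel1mec1, chk1rad53, dun1rad53 and chk1dun1, and the deletions crt1 and ste11. Sml1 inhibits ribonucleotide reductase, Crt1 (encoded by RFX1) represses the genes of that enzyme, and Ste11 is a kinase of the pheromone pathway. Strains are named by their labels, which do not say whether those without MEC1 or RAD53 also lack SML1. Differences of those strains from wild type may thus include an effect of a further deletion. The factor set holds 5 strains that each lack a transcription factor of another system: hap1, hap4, sut1, rcs1 (which lacks AFT1) and yap7. Each of the 18 strains had 2 replicates of 2 arrays with opposite dyes. All values are log2 of MMS over untreated, with direction taken from the dyes, an assumed base of 2 and an unknown centring. The deleted genes go against the label of 1 array, the one labelled dun1 replicate 2 with MMS in Cy5: DUN1 had 2.71 there, against -0.24 to -0.11 on the other 3 dun1 arrays, and MEC1 -2.34, against -0.75 to 0.30 on the other 51 arrays of the set. All values of dun1 include this array unless stated. The number of arrays limits the precision: the median 95% half-width was 0.197 for a response and 0.279 for a difference from wild type, and 0.153 and 0.171 in the factor set. Replicates correlated across genes, which are not independent, with r from 0.776 (chk1rad53) to 0.948 (chk1dun1) in the kinase set and from 0.902 to 0.937 in the factor set.

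The wild-type response shows what MMS does when the whole pathway is present. RNR3 (YIL066C), a subunit of ribonucleotide reductase, rose by 4.24 ± 0.07 (SD, n = 2) and HUG1 (YML058W-A), an inhibitor of that enzyme, by 4.07 ± 0.11. The cyanamide hydratase genes DDI3 (YFL061W) and DDI2 (YNL335W) rose by 3.88 ± 0.11 and 3.86 ± 0.14, and the sulfite pump gene SSU1 (YPL092W) by 3.16 ± 0.08. YNL134C (3.08), GTT2 (3.02), OSI1 (2.88), ARG1 (2.87) and YHB1 (2.81) completed the 10 highest. Among the 10 lowest, CYC1 (YJR048W), encoding cytochrome c, had a value of -3.86 ± 0.78, NDE1 -2.64 and CYB5 -2.63; SFG1 (-2.24), PHO5 (-2.23), HXT2 (-2.01), ERG5 (-2.00), EGT2 (-1.94), PHO3 (-1.93) and URA1 (-1.91) followed. In limma's fit the adjusted p was 5.8e-17 for RNR3 and 8.3e-12 for CYC1. Of 5594 genes, 2917 were called, 1498 higher and 1419 lower, and 273 of them changed at least 2-fold (175 higher, 98 lower).

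The fixed lists give this response by pathway, as means over their members in wild type. All 5 Crt1-repressed genes rose, with a mean of 2.54; RNR2 (YJL026W) rose by 1.65 ± 0.41, RNR4 (YGR180C) by 2.09 ± 0.21 and RFX1 (YLR176C) by 0.67. All 21 genes of the Yap1 oxidative stress list rose (mean 1.23; SRX1 2.41, ECM4 2.24, GPX2 2.04), as did all 34 proteasome genes (0.87; PRE3 1.38, RPT2 1.35) and 25 of 26 general stress genes of Msn2 and Msn4 (1.37; HSP12 2.60, TFS1 2.56, DDR2 2.10). In the heat shock list 11 of 22 rose and 0 fell (0.59; SSA4 1.89, HSP42 1.83). Of 38 DNA repair genes 19 rose and 1 fell (0.31; DIN7 1.33, DDI1 1.30, MAG1 1.20, RAD54 1.00), of 28 G1/S genes of the factor MBF 17 rose and 1 fell (0.41; RFA2 1.27, POL30 1.15), and of 22 iron regulon genes 13 rose and 3 fell (0.42; FIT2 1.29, TIS11 1.16, HMX1 -1.21). Of 37 amino acid genes of Gcn4, 18 rose and 4 fell (0.42; ARG3 2.27, ARG4 1.65, LYS4 -0.81).

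Growth and late cell cycle lists went the other way in wild type. M/G1 genes, expressed at cell separation, had a mean of -0.97 with 15 of 16 lower and 0 higher (ASH1 -1.86, DSE4 -1.65, PCL9 -1.63), and the mitotic CLB2 cluster -0.80 with 16 of 18 lower and 1 higher (HOF1 -1.85, HST3 -1.50, CHS2 -1.40). Histones had a mean of -0.71 (8 of 10 lower, 0 higher; HTB2 -1.45, HTA2 -1.24), ergosterol synthesis -0.67 (20 of 25 lower, 1 higher; MVD1 -1.17, HMG1 -1.07), ribosome biogenesis -0.65 (48 of 50 lower, 0 higher; NIP7 -1.03), respiration -0.48 (18 of 34 lower, 0 higher; COX5A -1.44, COX7 -1.10) and ribosomal proteins -0.24 (60 of 129 lower, 0 higher). These 16 lists passed limma's camera at the preset correlation. With an estimated correlation, Crt1-repressed genes (adjusted p 0.0378), M/G1 genes (0.00853) and the Yap1 list (0.0126) still passed, and for the other 13 lists the adjusted p lay between 0.0811 and 0.618.

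A further 9 lists did not pass camera in wild type, and their members went both ways or moved little. The means were 0.16 for checkpoint genes (8 of 20 higher, 4 lower), -0.18 for G1/S genes of the factor SBF (4 of 13 higher, 6 lower), 0.12 for multidrug resistance (3 of 10 higher, 2 lower), 0.03 for sulfur assimilation (9 of 21 higher, 6 lower; MET6 -1.28, SAM2 -1.19, MET2 0.95) and -0.22 for heme and oxygen genes (4 of 18 higher, 7 lower; YHB1 2.81, ANB1 -1.20). Pheromone response genes had a mean of -0.13 (3 of 25 higher, 8 lower; FAR1 -1.40), alpha-cell genes 0.14 (1 of 4 higher, 0 lower) and meiosis genes 0.13 (6 of 15 higher, 1 lower). Glycolysis genes had a mean of 0.04 and a median of -0.02, which differ in sign, with 2 of 16 higher and 2 lower. Counts adjusted over the list alone equalled those over all genes for the 25 lists except SBF genes (4 higher, 7 lower), the CLB2 cluster (1, 17), ribosomal proteins (0, 58), ergosterol synthesis (1, 21), heme and oxygen (5, 7), pheromone response (2, 8) and meiosis (5, 1).

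**Figure D1:**
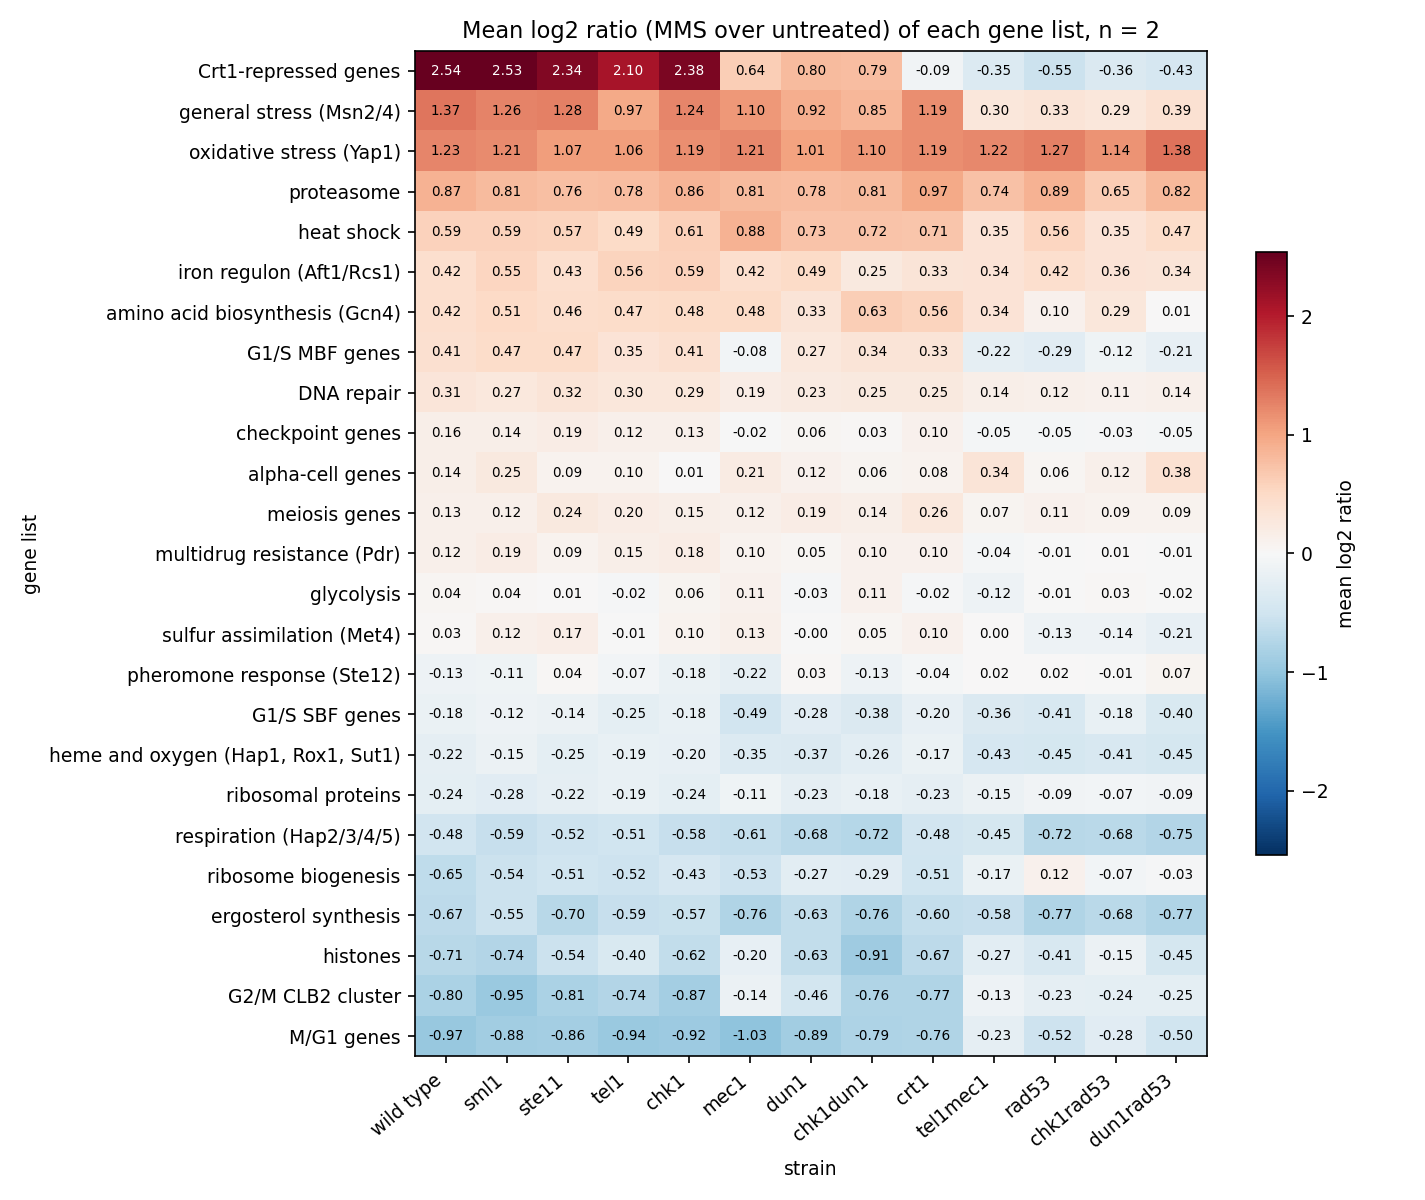
Mean log2 of MMS over untreated of the members of 25 gene lists (vertical axis) in the 13 strains of the kinase set (horizontal axis), with colour giving the mean of 2 replicates. The Crt1-repressed list goes from 2.54 in wild type to -0.55 in rad53, while the proteasome list stays between 0.65 and 0.97.

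Responses in the other strains show which parts of the wild-type pattern were present without each kinase. Yap1 targets and proteasome genes responded in every strain: list means lay between 1.01 (dun1) and 1.38 (dun1rad53) for Yap1 and between 0.65 (chk1rad53) and 0.97 (crt1) for the proteasome. Of the Yap1 list 17 to 21 of 21 were higher in each strain (17 to 21 over the list alone), of the proteasome 33 or 34 of 34 (34 over the list alone), and 0 were lower; with an estimated correlation the adjusted p lay between 0.00853 and 0.0202 for Yap1 and between 0.104 and 0.2 for the proteasome. DDI2 rose by between 3.12 ± 0.44 (crt1) and 4.58 ± 0.04 (tel1mec1) in 11 deletion strains and by 2.39 ± 0.09 in rad53. CYC1 fell in all 13 strains, from -2.16 ± 0.03 in tel1mec1 to -4.29 ± 0.56 in ste11, and CYB5 from -2.18 ± 0.15 in tel1mec1 to -2.91 ± 0.05 in ste11. The highest gene was HUG1 in sml1 (4.84), tel1 (4.30) and chk1 (4.96), RNR3 in ste11 (4.09), DDI2 in mec1 (4.02), dun1 (3.53) and crt1 (3.12), DDI3 in tel1mec1 (4.73), SRX1 in rad53 (3.31) and dun1rad53 (3.61), and SSU1 in chk1rad53 (3.41) and chk1dun1 (3.90).

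The size of the response, as the share of wild type kept over genes that changed at least 2-fold there, fell into a high and a low range. It was 1.02 ± 0.0418 (SD, n = 2) in sml1, 1.01 ± 0.0528 in chk1, 1.01 ± 0.0105 in ste11, 0.930 ± 0.0612 in tel1 and 0.881 ± 0.0281 in crt1. It was 0.807 ± 0.0981 in mec1, 0.791 ± 0.0327 in chk1dun1 and 0.770 ± 0.0618 in dun1 (0.727 without the array whose deleted gene goes against its label). The lowest shares were 0.496 ± 0.00244 in dun1rad53, 0.479 ± 0.0423 in rad53, 0.467 ± 0.0388 in tel1mec1 and 0.459 ± 0.161 in chk1rad53, whose replicates gave 0.345 and 0.573; its replicate 1 array with MMS in Cy3 had an SD over genes of 0.197 against 0.365 to 0.413 on the other 3. Taken for risen and fallen genes apart, the share was 0.701 and 0.932 in dun1 (0.641 and 0.931 without that array) and 0.441 and 0.571 in rad53. No test was made on these shares.

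**Figure D2:**
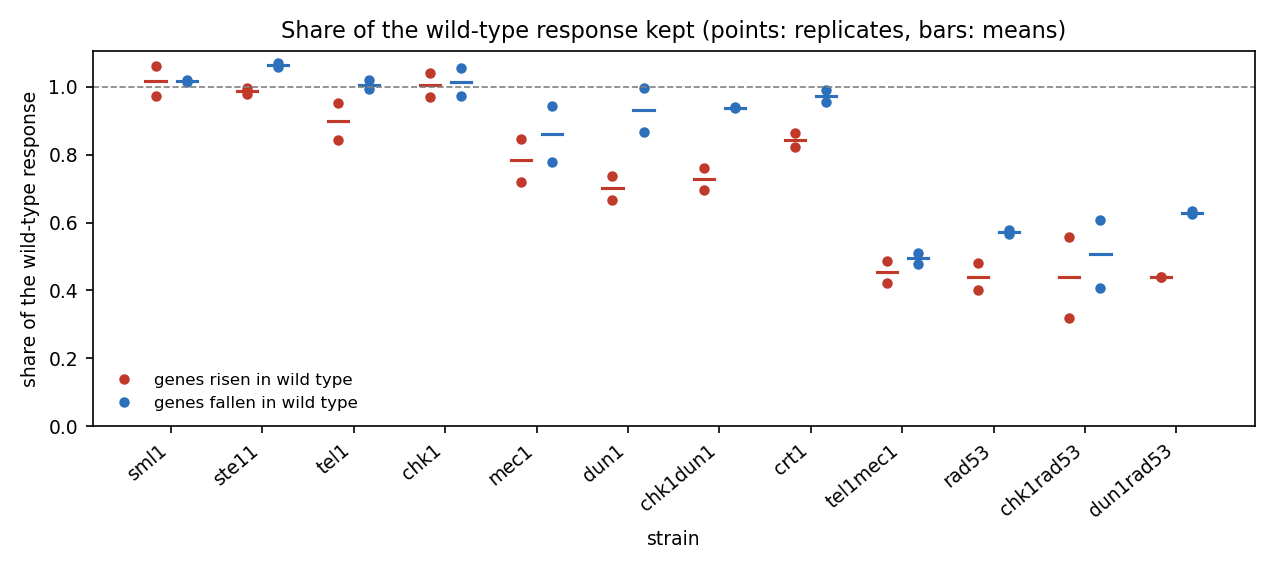
Share of the wild-type response kept (vertical axis, slope relative to wild type, no unit) in the deletion strains of the kinase set, for genes that rose and genes that fell in wild type; points are the replicates, bars their means, and the dashed line marks 1. Over all such genes rad53, tel1mec1, chk1rad53 and dun1rad53 lie between 0.459 and 0.496, the other strains between 0.770 and 1.02.

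Called genes in each strain numbered as follows. The counts were 2915 in sml1 (1509 higher, 1406 lower, 273 at least 2-fold), 2883 in ste11 (1568, 1315 and 281), 2831 in crt1 (1495, 1336 and 255), 2764 in chk1 (1464, 1300 and 273) and 2663 in tel1 (1440, 1223 and 228). They were 2455 in mec1 (1321, 1134 and 197), 2232 in dun1 (1220, 1012 and 149), 2170 in chk1dun1 (1178, 992 and 172), 1983 in rad53 (1066, 917 and 104), 1917 in dun1rad53 (1063, 854 and 87), 1789 in tel1mec1 (974, 815 and 68) and 1125 in chk1rad53 (627, 498 and 58). Leaving out a replicate lowered several counts by over 1.5 times: to 1638 without sml1 replicate 1, 973 without mec1 replicate 1, 1508 without chk1 replicate 2, 1774 without crt1 replicate 2, 1844 without ste11 replicate 1 and 126 without chk1rad53 replicate 2. Without 3 single arrays that stand apart (mec1 replicate 1 and the array labelled dun1 replicate 2 with MMS in Cy5, chk1rad53 replicate 1 with MMS in Cy3), chk1rad53 had 1916. Without replicate 1 or 2 they were 540 and 1012 in tel1mec1, 1147 and 1077 in rad53, 1322 and 1244 in dun1, 789 and 762 in dun1rad53, and 1117 and 957 in chk1dun1.

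With SML1, TEL1, CHK1 or STE11 deleted, 1 gene in all was called as different from wild type. RNR3 responded at 4.38 ± 0.22 (SD, n = 2) in sml1, 3.82 ± 0.28 in tel1, 4.26 ± 0.08 in chk1 and 4.09 ± 0.17 in ste11, beside 4.24 ± 0.07 in wild type. RNR4 had 0.92 in tel1 and 1.03 in chk1 against 2.09 in wild type, which limma did not call (adjusted p 0.886 and 0.994). The single gene was HUG1, higher in chk1 than in wild type, at 4.96 ± 0.15 against 4.07 ± 0.11, a difference of 0.90 (SE 0.14, adjusted p 0.013). That call was lost in each fit with a random block and when any one of wild type replicate 1, wild type replicate 2, chk1 replicate 1 or chk1 replicate 2 was left out; without wild type replicate 1 and without either chk1 replicate 0 genes were called. Limma called 0 genes for sml1, tel1 and ste11, where 138, 283 and 113 genes had an unadjusted p under 0.05, and 1 for chk1, where 247 had. Without tel1 replicate 1, and likewise without ste11 replicate 2, 1 gene was called.

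Small shifts of whole lists were seen in these 4 strains. In tel1 the general stress list stood at -0.40 relative to wild type and histones at 0.32, with 0 members called over all genes, and 4 lower and 2 higher adjusted over the list alone. Ribosome biogenesis genes stood at 0.22 in chk1 and pheromone response genes at 0.17 in ste11, with 0 called over all genes, and 0 and 3 higher adjusted over the list alone. Each passed camera at the preset correlation, and with an estimated correlation the adjusted p was 0.178 for stress and 0.314 for histones in tel1, 0.459 in chk1 and 0.314 in ste11. In sml1 the respiration list stood at -0.11 and the CLB2 cluster at -0.15, with 0 called over all genes and over the list alone (estimated-correlation p 0.314 and 0.548). On the 2 slides that held both strains, sml1 minus wild type was 0.50 and 0.11 for the Crt1-repressed list, against -0.01 over all arrays.

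In mec1 most of the increase of ribonucleotide reductase genes and of the decrease of mitotic genes was absent. RNR3 responded at 1.00 ± 0.08 (SD, n = 2) in mec1 against 4.24 ± 0.07 in wild type, a difference of -3.24 (SE 0.15, adjusted p 1.5e-11), and HUG1 at 1.39 against 4.07. RNR1 had -0.16 ± 0.06 against 1.64 ± 0.17, RNR4 0.18 against 2.09, RNR2 0.29 against 1.65, and the further lower genes were PLM2 (-1.49), ATR2 (-1.44), the S-phase cyclin gene CLB6 (-1.16), YPR015C (-1.02) and VVS1 (-0.99). Higher in mec1 were genes of cytokinesis and mitosis that fell in wild type: HOF1 (-0.10 against -1.85, difference 1.74), CHS2 (1.31), SWI5 (1.17) and the histone gene HTB2 (1.13), with YNL058C (1.54), IRC8 (1.51), PUL3 (1.41), YML119W (1.39), AIM20 (1.10) and HSP30 (1.07). The kinase gene DUN1 (YDL101C) responded at 0.52 against 1.55.

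By list, mec1 minus wild type was -1.91 for Crt1-repressed genes (0 higher, 4 of 5 lower; 5 lower adjusted over the list alone), -0.48 for MBF genes (0 higher, 10 of 28 lower; 18 over the list alone) and 0.66 for the CLB2 cluster (11 of 18 higher; 14 over the list alone). These 3 passed with an estimated correlation as well (adjusted p 0.00287, 0.0214 and 0.0488). SBF genes stood at -0.31 (4 of 13 lower; 6 over the list alone) and histones at 0.51 (1 of 10 higher; 8 over the list alone), with an estimated-correlation p of 0.123 and 0.137. In all 87 genes were called, 28 higher and 59 lower, and 20 at least 2-fold. The count was 50 without wild type replicate 2, 38 without mec1 replicate 1, 45 without mec1 replicate 2 and 139 without the 3 single arrays. RNR4 lost its call when any of the 4 replicates was left out, RNR2 without wild type replicate 1 or either mec1 replicate, HSP30 without either wild type replicate, mec1 replicate 1 or the 3 single arrays (0.39), VVS1 without wild type replicate 2 or either mec1 replicate, and HTB2 without wild type replicate 2 or mec1 replicate 1.

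With TEL1 lost in addition to MEC1, the RNR3 and HUG1 increase was absent. In tel1mec1 RNR3 had -0.62 ± 0.13 (SD, n = 2) and HUG1 -0.58 ± 0.09, differences from wild type of -4.86 (SE 0.15) and -4.64 (SE 0.14), both with an adjusted p of 3.4e-15. The stress genes HSP12 (-0.06 against 2.60 in wild type), DDR2 (-0.15 against 2.10), RTC3 (0.24 against 2.55) and FMP16 (-0.46 against 2.04) were among the 10 lowest differences, while the general stress list had a mean of 0.30 in tel1mec1 (10 of 26 higher, 1 lower; the same over the list alone; estimated-correlation p 0.456). RNR1 (-2.25), RNR2 (-2.07), RNR4 (-2.29) and PLM2 (-2.23) were also among the 10 lowest differences. The 10 highest were HOF1 (1.93), the cell wall gene PIR1 (1.73), CYC1 (1.71), EGT2 (1.65), YNL058C (1.47), SHM2 (1.47), PHO89 (1.44), ASH1 (1.42), ADE1 (1.40) and YML119W (1.40), all of which fell in wild type.

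Relative to wild type, the tel1mec1 lists stood at -2.89 for Crt1-repressed genes (5 of 5 lower; 5 over the list alone), -1.07 for general stress (18 of 26 lower; 25 over the list alone), -0.63 for MBF genes (18 of 28 lower; 23 over the list alone), 0.74 for M/G1 genes (12 of 16 higher; 12 over the list alone), 0.67 for the CLB2 cluster (12 of 18 higher, 1 lower; 15 and 2 over the list alone) and 0.48 for ribosome biogenesis (22 of 50 higher; 37 over the list alone). With an estimated correlation Crt1-repressed genes (adjusted p 0.00579) and M/G1 genes (0.00547) passed, and the other four lists had an adjusted p of 0.123, 0.0662, 0.246 and 0.424. Called were 722 genes, 283 higher and 439 lower, 118 at least 2-fold. Without wild type replicate 2 the count was 396, without tel1mec1 replicate 1 309 and without tel1mec1 replicate 2 363. PHO89 lost its call without wild type replicate 1, and CYC1 and PHO89 when arrays were scaled to one spread.

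Set directly against mec1, tel1mec1 differed in cell separation and stress genes. Cell separation genes, low in mec1, were near 0 in tel1mec1: EGT2 -0.28 ± 0.14 against -2.07 ± 0.03 (SD, n = 2), PIR1 -0.15 against -2.11 and SCW11 -0.16 against -1.66. HUG1 (-0.58 against 1.39), RTC3 (difference -1.76) and DDR2 (-0.15 against 1.51) were lower. The M/G1 list differed by 0.80 (10 of 16 higher; 10 over the list alone; estimated-correlation p 0.000277) and Crt1-repressed genes by -0.98 (2 of 5 lower; 3 over the list alone; p 0.032). General stress differed by -0.80 (11 of 26 lower; 21 over the list alone) and heat shock by -0.54 (5 of 22 lower; 10 over the list alone), with p 0.0665 and 0.079. The mec1 replicate 1 array with MMS in Cy5 had a stress mean of 1.97 against 0.68 to 1.01 on the other 3; without the 3 single arrays that stand apart, this one included, stress differed by -0.49 and heat shock by -0.31 (p 0.175 in each). On the slide holding both strains, 1 array of each with MMS in Cy3, the differences were 0.71 for M/G1, -0.88 for Crt1-repressed genes, -0.66 for stress and -0.58 for heat shock.

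Of the 133 genes called between tel1mec1 and mec1, 37 were higher and 96 lower, and 36 differed at least 2-fold. This count was 28 without mec1 replicate 1, 230 without mec1 replicate 2, 55 without tel1mec1 replicate 1, 30 without tel1mec1 replicate 2 and 84 without the 3 single arrays. DDR2 lost its call without mec1 replicate 1 and without either tel1mec1 replicate.

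In rad53 the response of 1183 genes differed from that of wild type. RNR3 had -0.59 ± 0.11 (SD, n = 2) in rad53 and HUG1 -0.56 ± 0.29, differences of -4.83 (SE 0.15) and -4.63 (SE 0.14), both with an adjusted p of 3.8e-15. RNR4 (-0.65 against 2.09), RNR2 (-0.83 against 1.65) and RNR1 (-0.76 against 1.64) were below 0 where wild type was above, and the stress genes HSP12 (0.17 against 2.60), FMP16, RTC3 and PGM2 (0.10 against 2.15) and the gene PLM2 made up the rest of the 10 lowest. The 10 highest were HOF1 (1.77), YNL058C (1.64), PHO5 (1.56), PHO89 (1.49), IRC8 (1.43), NDE1 (1.41), YML119W (1.36), the purine gene ADE1 (1.33), the ribosome assembly gene FAF1 (1.25) and HOS2 (1.24). The DUN1 response was -0.01 in rad53 against 1.55 in wild type.

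The rad53 lists stood at -3.09 for Crt1-repressed genes (5 of 5 lower; 5 over the list alone), -1.04 for general stress (22 of 26 lower; 24 over the list alone), -0.69 for MBF genes (20 of 28 lower; 22 over the list alone), 0.76 for ribosome biogenesis (48 of 50 higher; 48 over the list alone), 0.57 for the CLB2 cluster (12 of 18 higher, 2 lower; 13 and 2 over the list alone) and 0.45 for M/G1 genes (10 of 16 higher, 1 lower; 11 and 1 over the list alone), relative to wild type. With an estimated correlation Crt1-repressed genes passed (adjusted p 0.00758), and the others had an adjusted p of 0.162, 0.0807, 0.282, 0.314 and 0.0636. In all 1183 genes were called, 574 higher and 609 lower, 129 at least 2-fold. The count was 663 without wild type replicate 2 and 567 without rad53 replicate 2. Over the alternatives the M/G1 mean lay between 0.11 and 0.48, with an adjusted camera p up to 0.29. PHO5 and NDE1 lost their calls when arrays were scaled to one spread, and HOS2 with sml1 as the reference.

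Removing CHK1 or DUN1 in addition to RAD53 changed little. In chk1rad53 HUG1 (-4.54), RNR3 (-4.40) and RNR4 (-2.60) were the lowest differences from wild type and HOF1 (1.68), EGT2 (1.56) and HTB2 (1.46) the highest. In dun1rad53 RNR3 (-4.72), HUG1 (-4.51) and ARG1 (-2.60) were lowest and the aryl-alcohol dehydrogenase gene AAD6 (3.27 against 1.49), HOF1 (1.69) and YNL058C (1.60) highest. Crt1-repressed genes stood at -2.91 and -2.97 relative to wild type (5 of 5 lower in each, 5 over the list alone), general stress at -1.08 (21 of 26 lower; 22 over the list alone) and -0.98 (18 lower; 22), M/G1 genes at 0.69 (13 of 16 higher; 13) and 0.47 (10 higher, 1 lower; 11 and 1), MBF genes at -0.52 (15 of 28 lower; 19) and -0.61 (18 lower; 19) and ribosome biogenesis at 0.58 (30 of 50 higher; 45) and 0.62 (37 higher; 46). Under an estimated correlation the Crt1 list (adjusted p 0.00579 in both strains) and the M/G1 list (0.00579 and 0.0488) passed, and p lay between 0.103 and 0.314 for the rest; without the 3 single arrays the M/G1 list of chk1rad53 had 0.62 and p 0.0567. Over the alternatives the M/G1 mean of dun1rad53 lay between 0.10 and 0.49, with an adjusted camera p up to 0.41.

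Called relative to wild type were 785 genes in chk1rad53 (353 higher, 432 lower, 95 at least 2-fold) and 902 in dun1rad53 (424 higher, 478 lower, 105 at least 2-fold). The chk1rad53 count was 424 without wild type replicate 2 and 293 without chk1rad53 replicate 1. The dun1rad53 count was 481 without wild type replicate 2, 311 without dun1rad53 replicate 1 and 383 without dun1rad53 replicate 2, and ARG1 lost its call in these 3 cases. Against rad53 itself limma called 0 genes for either strain, with 322 and 136 genes at an unadjusted p under 0.05. Leaving out rad53 replicate 1 gave 1 and 2 calls, and leaving out rad53 replicate 2 gave 2 and 4. M/G1 genes were higher in chk1rad53 than in rad53 by 0.24 (0 of 16 called; 4 higher over the list alone; estimated-correlation p 0.032; 0.18 with p 0.296 without the 3 single arrays, where 2 genes were called), and alpha-cell genes higher in dun1rad53 by 0.33 (0 of 4 called; 1 over the list alone; p 0.0466). On the slide with both dun1rad53 and rad53 the Crt1-repressed list differed by -0.06 and general stress by 0.13, against 0.12 and 0.06 over all arrays.

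The direct contrast of mec1 with rad53 sets the upstream kinase against the downstream one without the shared wild-type replicates. HUG1 was higher in mec1 (1.39 ± 0.08 against -0.56 ± 0.29, SD, n = 2; adjusted p 4.4e-08), as were DDI3 (3.97 against 2.32) and DDI2 (4.02 against 2.39). BSC1 (-0.98 against 0.47), NDE1 (-2.67 against -1.23) and PRM7 (-0.97 against 0.35) were lower. Crt1-repressed genes differed by 1.18 (4 of 5 higher; 4 over the list alone), general stress by 0.77 (17 of 26 higher; 20 over the list alone), ribosome biogenesis by -0.65 (40 of 50 lower; 49 over the list alone) and M/G1 genes by -0.51 (9 of 16 lower; 9 over the list alone). With an estimated correlation the adjusted p was 0.032 for the Crt1 list, 0.137 for stress, 0.18 for ribosome biogenesis and 0.0139 for M/G1. On the 1 slide that held both strains with MMS in the same dye, Cy5, these lists differed by 1.22, 1.70, -1.11 and -0.57. The mec1 array there, replicate 1, had an SD over genes of 0.607 against 0.408 to 0.420 on the other mec1 arrays, and a stress mean of 1.97 against 0.73 on its dye-swap partner. Without the 3 single arrays, this one included, the differences were 1.17, 0.46, -0.52 and -0.46, with p 0.018, 0.291, 0.188 and 0.0615.

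Called between mec1 and rad53 were 489 genes, 220 higher in mec1 and 269 lower, 41 of them at least 2-fold. With the slide as a random block the count was 264. It was 19 without mec1 replicate 1, 286 without rad53 replicate 1, 79 without rad53 replicate 2 and 235 without the 3 single arrays. BSC1 and PRM7 lost their calls in each of these 4 cases, and NDE1 without mec1 replicate 1.

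The lowest differences after loss of DUN1 were in RNR3 and HUG1, which kept their calls without the array whose deleted gene goes against its label. RNR3 responded at 1.29 ± 0.32 (SD, n = 2) in dun1 against 4.24 ± 0.07, a difference of -2.95 (SE 0.15, adjusted p 8.8e-11), and HUG1 at 1.49 ± 0.03 against 4.07. RNR2 had 0.33 against 1.65, a difference of -1.32. RNR4 differed by -1.58 and was not among the named genes (-1.28 without that array, limma's adjusted p 0.171). On the slide that held 1 array of each strain with MMS in Cy3, RNR2 differed by only -0.31, RNR4 by -0.81, RNR3 by -2.43 and HUG1 by -1.65. Another slide held dun1 and ste11. There RNR2 and RNR4 differed by -0.54 and -0.66 with MMS in Cy5, but by 0.40 and 0.49 with MMS in Cy3. RNR3 and HUG1 were lower in dun1 with both dyes there. ATR2 (-1.27), OSI1 (-1.22), the peroxiredoxin gene TSA2 (0.73 against 1.90), GCY1 (-1.12), RTN2 (-1.05), PGM2 (-0.97) and ALD3 (-0.97) completed the 10 lowest named genes, and FES1 (0.66), YML119W (0.62) and IDI1 (0.49) were the 3 higher genes. RNR1, which did not rise in mec1 or rad53, responded at 0.96 in dun1, with -0.23 on the array labelled dun1 replicate 2 with MMS in Cy5 and 0.87 to 1.78 on the other 3; without that array it was 1.47, and 1.64 in wild type. In chk1dun1 RNR3 (-3.27) and HUG1 (-3.14) were again lowest, the purine gene ADE4 (0.92) and HMS2 (0.82) were higher, and DUN1 itself, deleted there, had -0.10 against 1.55.

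Crt1-repressed genes stood at -1.74 in dun1 (3 of 5 lower; 5 over the list alone) and -1.76 in chk1dun1 (2 lower; 4 over the list alone) relative to wild type, both past the test with an estimated correlation (adjusted p 0.00462 in each). General stress stood at -0.45 (4 of 26 lower; 8 over the list alone) and -0.52 (4 lower; 10 over the list alone), and ribosome biogenesis at 0.38 (0 of 50 called; 19 higher over the list alone) and 0.36 (0 called; 3 over the list alone), with an estimated-correlation p of 0.29 and 0.231 for stress and 0.314 for each ribosome list. Over the alternatives the stress mean lay between -0.81 and -0.06 in dun1 (adjusted camera p up to 0.18) and between -0.60 and -0.06 in chk1dun1 (up to 0.52). On the slide holding dun1 and wild type the Crt1 list differed by -1.05 and stress by -0.80. Called were 33 genes in dun1 (3 higher, 30 lower, 8 at least 2-fold) and 29 in chk1dun1 (2 higher, 27 lower, 14 at least 2-fold). With arrays scaled to one spread dun1 had 1 call, RNR3, and chk1dun1 3.

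The array labelled dun1 replicate 2 with MMS in Cy5, with DUN1 at 2.71 and MEC1 at -2.34, enters these dun1 values. The other 83 values of deleted genes in the strains that lack them lay between -1.34 and 0.37, and this array correlated less with the other dun1 arrays (median r 0.624 against 0.769 to 0.791). RNR3 and HUG1 stood at 0.72 and 1.11 on it, 1.40 and 1.83 on its partner, and 1.51 and 1.52 in replicate 1. Its Crt1 list mean was 0.35 against 0.84 to 1.03 on the other 3 dun1 arrays, and its stress mean 1.80 against 0.35 to 0.87. Without this array RNR3 differed from wild type by -2.78, HUG1 by -2.39, RTN2 by -1.61 and PGM2 by -1.47, and YML119W lost its call (0.30). The count of dun1 against wild type was then 69 (10 higher, 59 lower, 26 at least 2-fold), and 116 without the 3 single arrays. The Crt1 list stood at -1.59 (3 of 5 lower; 4 over the list alone) and general stress at -0.81 (9 of 26 lower; 20 over the list alone), with an estimated-correlation p of 0.00513 and 0.0904 (0.0034 and 0.0305 without the 3 single arrays). Between chk1dun1 and dun1 limma then called 0 genes, with 136 at an unadjusted p under 0.05.

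Single replicates moved these counts. For dun1 it was 15 without wild type replicate 1, 14 without wild type replicate 2, 94 without dun1 replicate 1 and 8 without dun1 replicate 2, and FES1, YML119W, IDI1, PGM2 and ALD3 lost their calls without either wild type replicate or without dun1 replicate 2, ALD3 also without dun1 replicate 1. RNR2 and OSI1 lost theirs without wild type replicate 1 or dun1 replicate 2. For chk1dun1 the count was 10 without wild type replicate 2, 6 without chk1dun1 replicate 1 and 7 without chk1dun1 replicate 2; ADE4 and HMS2 lost their calls without any one of the 4 replicates and DUN1 without either chk1dun1 replicate. Between chk1dun1 and dun1 limma called 0 genes, with 181 at an unadjusted p under 0.05, and 53 without dun1 replicate 1. The iron regulon stood lower in chk1dun1 than in dun1 by -0.24 (0 of 22 called; 4 lower over the list alone; estimated-correlation p 0.032, 0.0444 without the array labelled dun1 replicate 2 with MMS in Cy5 and 0.0567 without the 3 single arrays).

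Without the repressor Crt1 its target genes no longer responded to MMS. The ratios do not show the level of these genes in untreated crt1 cells. In crt1 RNR3 had -0.04 ± 0.04 (SD, n = 2), HUG1 -0.03 ± 0.06, RNR4 -0.05 ± 0.01 and RNR2 -0.15 ± 0.21, differences from wild type of -4.28 (SE 0.15, adjusted p 3.8e-14), -4.10, -2.14 and -1.80. ATR2 (-2.21), the proline permease gene PUT4 (-1.48), YPR015C (-1.47), GUP2 (-1.20), the ammonium transporter gene AMF1 (-1.13) and YDL085C-A (-0.93) were also lower, and ASH1 (0.59) was the 1 higher gene. PUT4 had -1.96 against -0.49. RFX1, deleted in this strain, had a difference of -0.82. All 5 Crt1-repressed genes were called lower (mean -2.63, 5 over the list alone, estimated-correlation p 0.000395). RFX1 is 1 of these 5, and its lower value may come from its deletion alone. The list mean, the list p and the count of lower genes given below include it. General stress stood at -0.18 relative to wild type and MBF genes at -0.07, with 0 members called by limma over all genes, and 0 and 1 lower over the list alone (estimated-correlation p 0.75 and 0.768). For crt1 and the other contrasts without a slide value here, no slide held both strains with MMS in the same dye; on the slide that held crt1 and sml1 the Crt1 list differed by -2.72 with MMS in Cy5 and -2.15 with MMS in Cy3.

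In all 15 genes were called between crt1 and wild type, 1 higher and 14 lower, 9 at least 2-fold, and 82 without crt1 replicate 1. RNR4 lost its call when any of the 4 replicates was left out, RNR2 and ASH1 without wild type replicate 1 or crt1 replicate 2, and PUT4 without wild type replicate 2.

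**Figure D3:**
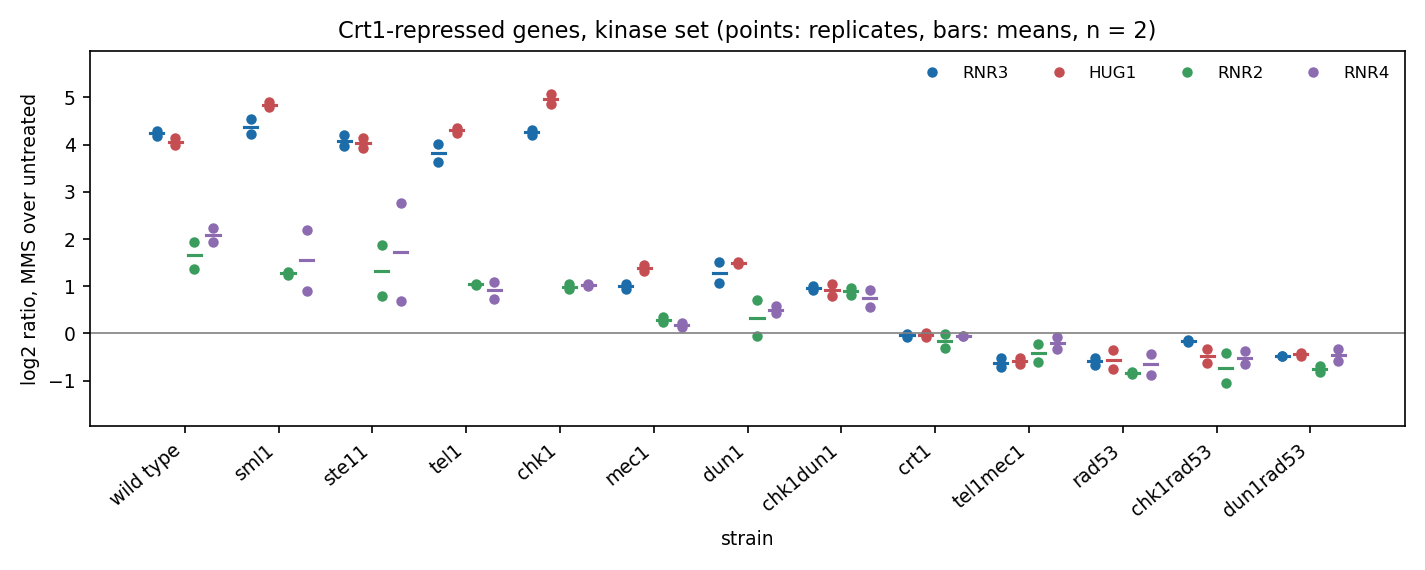
Log2 of MMS over untreated (vertical axis) of the Crt1-repressed genes RNR3, HUG1, RNR2 and RNR4 in the 13 strains of the kinase set; points are the 2 replicates and bars their means. RNR3 stands at 4.24 in wild type, 1.29 in dun1 (1.46 without the array whose deleted gene goes against its label), 1.00 in mec1, -0.04 in crt1 and -0.59 in rad53.

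In the factor set the question was whether regulators of respiration, sterol uptake, iron and nitrosative stress shape the MMS response. All 5 strains responded to MMS, with no wild type in this table to say what was kept. HUG1 rose by 5.05 ± 0.09 (hap4) to 5.20 ± 0.06 (rcs1) (SD, n = 2), SSU1 by 3.24 (hap4) to 3.74 (rcs1), RNR3 by 3.15 (hap4) to 3.79 (sut1) and DDI2 by 2.95 (yap7) to 4.59 (hap4). SFG1 fell in each strain (from -2.38 in hap1 to -2.70 in rcs1), as did CYC1 in 4 of them (-3.44 in rcs1 to -4.09 in hap4). All 34 proteasome genes rose in each strain (means 0.84 to 0.94), and histones fell (-0.94 to -1.17, 8 or 9 of 10 lower). With an estimated correlation 0 of 125 list tests passed in these responses, against 77 with limma's preset correlation. Called were 3192 genes in hap1 (1684 higher, 1508 lower, 224 at least 2-fold), 3102 in hap4 (1640, 1462 and 226), 2642 in sut1 (1383, 1259 and 192), 3184 in rcs1 (1656, 1528 and 256) and 3111 in yap7 (1645, 1466 and 241; 1980 without yap7 replicate 2).

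Each factor strain was then compared with the mean of the other four, since no wild type was in this table. In hap1, which lacks a heme-dependent activator, the respiratory genes CYC1 and NDE1 hardly changed under MMS. CYC1 had -0.16 ± 0.10 (SD, n = 2) against -3.88 in the others, a difference of 3.71 (SE 0.10, limma's adjusted p 3.9e-08). NDE1 had -0.02 against -2.11, and the small uncharacterised gene YER053C-A 2.30 against -0.58. The ratios do not show whether CYC1 and NDE1 were already low in untreated hap1 cells. HES1 (-0.54), TIP1 (-0.50) and TIR1 (-0.49) were lower. Of the respiration list 9 of 34 still fell in hap1 (7 over the list alone) and 0 rose, and of ergosterol synthesis 10 of 25 fell and 4 rose (10 and 5 over the list alone). The respiration list stood at 0.53 relative to the others (16 of 34 higher; 21 over the list alone) and ergosterol synthesis at 0.51 (13 of 25 higher; 21 over the list alone), with an estimated-correlation p of 0.215 and 0.207. The heme and oxygen list had a mean of 0.32 and a median of -0.01. Called were 90 genes, 73 higher and 17 lower, 10 at least 2-fold; the count was 51 without hap1 replicate 1 and 42 without hap1 replicate 2. HES1, TIP1 and TIR1 lost their calls without hap1 replicate 1, and TIP1 and TIR1 also without hap1 replicate 2.

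In hap4, which lacks an activator of respiratory genes, DDI2 (4.59 ± 0.19 against 3.16), DDI3 (1.03) and the cell cycle inhibitor gene FAR1 (-0.10 ± 0.02 against -1.20 ± 0.10, SD, n = 2; adjusted p 0.0002) were higher than in the other four strains. EGO4 (-1.32), GAL1 (-1.24 against -0.18) and CYC7 (-0.89) were lower. The pheromone response list stood at 0.20 (6 of 25 higher, 1 lower; the same over the list alone; FAR1 1.09, BAR1 0.91), ergosterol synthesis at -0.24 (3 of 25 lower; 14 over the list alone) and general stress at -0.33 (1 of 26 lower; 15 over the list alone), with an estimated-correlation p of 0.207, 0.292 and 0.46. Ergosterol synthesis responded at -0.70 in hap4, -0.10 in hap1, which enters the reference, and -0.53 to -0.63 in the other strains. In all 133 genes were called, 52 higher and 81 lower, 7 at least 2-fold, and 43 without hap4 replicate 1 and 9 without hap4 replicate 2. DDI2, EGO4 and CYC7 lost their calls without hap4 replicate 2 and DDI3 without either replicate.

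In rcs1, which lacks the iron regulator Aft1, siderophore uptake genes did not respond: FIT2 had 0.13 ± 0.04 (SD, n = 2) against 2.43 in the other four strains, a difference of -2.30 (SE 0.13, adjusted p 4e-05), SIT1 0.11 against 1.60 and ARN2 0.04 against 1.22. The iron regulon stood at -0.43 (0 higher, 5 of 23 lower; 3 and 13 over the list alone; ARN1 -1.13, TIS11 -1.02) and general stress at 0.37 (1 of 26 higher; 16 over the list alone), with an estimated-correlation p of 0.292 and 0.334. GPH1 (0.66), AAC1 (0.56) and PNS1 (0.50) were the highest of 4 higher genes, each losing its call without either rcs1 replicate. In all 15 genes were called, 11 lower and 5 at least 2-fold, and 7 without rcs1 replicate 2.

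In sut1, which lacks a regulator of sterol uptake, and in yap7, which lacks a repressor of YHB1, few genes differed. PHM6 (0.45), FCY22 (0.39) and YML018C (0.37) were higher in sut1, and TMA10 (0.05 ± 0.25 against 1.23, SD, n = 2), CIP1 (-0.75) and HAP4 (-0.69) lower. The arrays of a dye-swap pair disagreed on HAP4. With MMS in Cy5 and in Cy3 it had -0.32 and -1.72 in sut1 replicate 1, and -1.66 and -0.14 in replicate 2. The low values came with opposite dyes, so a constant dye effect does not give them. Averaging each pair hides this spread from the fit, so the HAP4 call is not secure. What sets these arrays apart was not tested, nor whether it affects other genes of sut1. The hap4 strain, which lacks HAP4, enters its reference with values between -0.13 and 0.29. In all 15 genes were called in sut1 (4 higher, 11 lower, 3 at least 2-fold). Without sut1 replicate 1 limma called 9 genes, 4 of them among the 15, and without sut1 replicate 2 it called 0, when 6 of 6 named genes lost their calls; CIP1 alone of them kept it without replicate 1. Ribosome biogenesis stood at 0.31 in sut1 (0 of 50 called; 39 higher over the list alone) and respiration at -0.23 (1 of 34 lower; 15 over the list alone), with an estimated-correlation p of 0.405 and 0.358. Respiration responded at -0.68 in sut1, -0.07 in hap1, which enters the reference, and -0.53 to -0.61 in the other strains. In yap7 the nitric oxide dioxygenase gene YHB1 rose to 4.13 ± 0.14 against 3.25 (difference 0.88, SE 0.08, adjusted p 0.0027), ARN2 to 1.53 against 0.85, and CYC1, whose yap7 values lay within the range of the other strains, differed by -0.98. These 3 calls were lost without yap7 replicate 2, and that of ARN2 also without replicate 1. The hap1 strain enters the reference for CYC1 with a value near 0, and rcs1 that for ARN2.

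**Figure D4:**
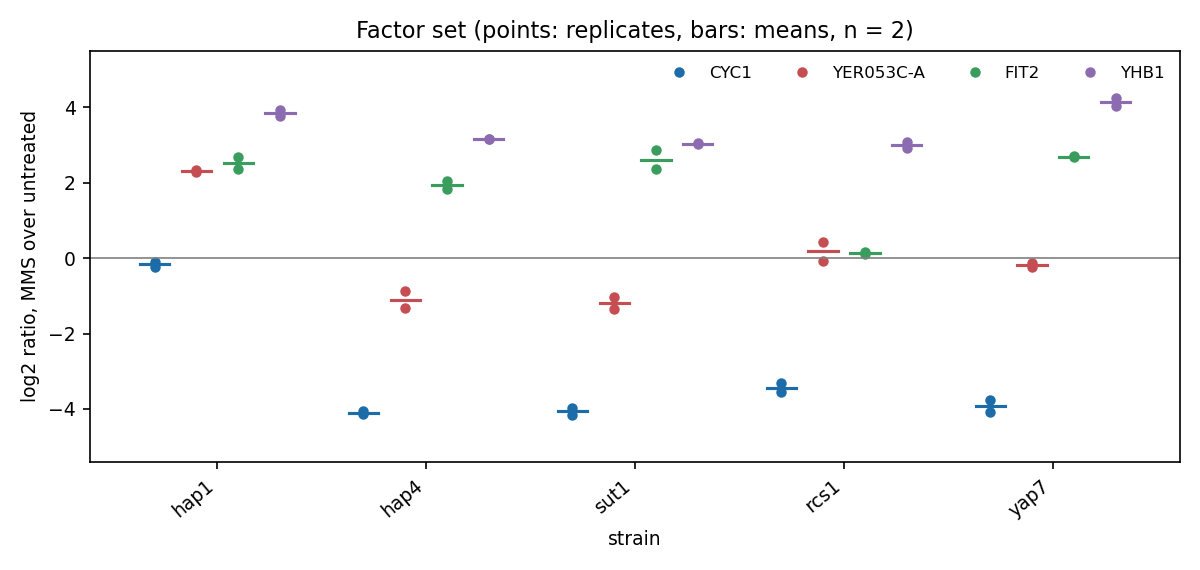
Log2 of MMS over untreated (vertical axis) of CYC1, YER053C-A, FIT2 and YHB1 in the 5 strains of the factor set (horizontal axis); points are the 2 replicates and bars their means. CYC1 stands at -0.16 in hap1 and from -3.44 to -4.09 in the other four strains, and FIT2 at 0.13 in rcs1.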

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

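All tests in this part but the slide test of tel1mec1 were chosen after the results were seen, or, for the splits of the replicates, after splits of the single arrays.

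Single arrays stood far from the other 3 of their strain in 10 genes and, once, in the spread over genes. On the wild type replicate 1 array with MMS in Cy3, CYC1 was -5.30 (others -3.53 to -3.30), SFG1 -1.26 (-2.62 to -2.52) and URA1 -0.83 (-2.41 to -2.19). On the tel1mec1 replicate 1 array with MMS in Cy3, YNL058C was 0.25 (others 0.05 to 0.07), RNR3 -0.91 (-0.53 to -0.51) and HUG1 -0.80 (-0.52 to -0.47). On the array labelled dun1 replicate 2 with MMS in Cy5, whose deleted gene goes against its label, YML119W was 0.28 (others -1.02 to -0.90). In crt1 replicate 2, RNR4 was -0.0273 with MMS in Cy3 (others -0.07 to -0.06), and with MMS in Cy5 PUT4 was -1.38 (-2.22 to -2.12) and YDL085C-A -1.24 (-0.47 to -0.36). The SD over genes was 0.607 on the mec1 replicate 1 array with MMS in Cy5 (others 0.408 to 0.420). These 11 were found among 140 groups of 4 arrays by the gap to the nearest array relative to the range (Dixon's test at 95%), and chance picks out about 1 in 20 such groups. The RNR4 and YNL058C values differ from the other arrays by little in log2.

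Differences between strains in the response were found by limma's test of the difference itself. Relative to wild type, 87 genes differed in mec1, 722 in tel1mec1, 1183 in rad53, 1 in chk1, 33 in dun1, 785 in chk1rad53, 902 in dun1rad53, 29 in chk1dun1 and 15 in crt1. Between tel1mec1 and mec1 133 genes differed, and between mec1 and rad53 489. Relative to the other four strains of the factor set 90 genes differed in hap1, 133 in hap4, 15 in sut1, 15 in rcs1 and 3 in yap7.

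Other splits of the replicates, the dye-swap pairs averaged, were counted for each contrast in a fit of its own strains. In the kinase set 2 against 2 replicates make 3 splits, too few for a share under 0.05. The real split called 27 genes for mec1, 396 for tel1mec1, 635 for rad53, 3 for dun1, 340 for chk1rad53, 653 for dun1rad53, 30 for chk1dun1 and 11 for crt1 against wild type, 95 for tel1mec1 against mec1 and 11 for mec1 against rad53; in each of these 1 of 3 splits called as many and the highest other split called 0. For sml1, tel1, chk1 and ste11 against wild type, chk1rad53 and dun1rad53 against rad53 and chk1dun1 against dun1 the real split called 0 in limma, so that 3 of 3 reach it by construction; the highest other split called 101 for ste11, 2 for chk1rad53 and 0 for the rest.

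Splits of the single arrays with a dye term were made first and then set aside, since the arrays of a dye-swap pair are not independent. Of 34 such splits 1, the real one, called as many genes for rad53 against wild type, tel1mec1 against mec1 and mec1 against rad53, and for rcs1 3 of 100 did; no verdict is drawn from these. In 11 of the 12 contrasts with wild type the split with the most genes, up to 1536, parted the arrays by dye with wild type replicate 1 exchanged. Since these fits hold a dye term, this points to a dye effect in wild type replicate 1 unlike that of the other pairs. The dye effect had an SD over genes of 0.391 in that pair, 0.401 in ste11 replicate 2 and 0.412 in crt1 replicate 2. The next highest in the kinase set was 0.223, in tel1 replicate 2. One of the 2 wild-type replicates thus comes from a pair of arrays unlike most others.

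In the factor set 2 against 8 replicates make 45 splits. The share of splits that called as many genes was under 0.05 for hap1 (1 of 45 splits, 55 genes, highest other 38) and hap4 (2, 38, 55). This does not exclude chance, since 5 strains were tested without adjustment and the replicates are not known to be separate cultures. For rcs1 the share was not under 0.05 (3, 10, 55). The other splits that reached its count were the hap1 and hap4 pairs of replicates, and none of the 40 splits that mix strains called over 4 genes. For sut1 (45; 0; 55) and yap7 (45; 0; 55) the real split called 0 in limma, so that 45 of 45 reach it by construction and nothing follows. The highest other split was the hap4 pair of replicates for hap1 and the hap1 pair for the other four strains, so strain differences enter these comparisons.

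Probes without a gene name, left out of all comparisons, responded as well. In wild type 146 of 649 were called (5 at least 2-fold, 3 higher and 2 lower), and in hap1 224 of 647 (9 at least 2-fold, 8 higher and 1 lower). Their genes were not analysed here.

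The general stress list responded less in tel1mec1 than in mec1 (0.30 against 1.10), though the list difference had an estimated-correlation p of 0.0665. One mec1 array, replicate 1 with MMS in Cy5, had 1.97; without it mec1 had 0.79 and the difference was -0.490 (spread 0.122), so this array carries part of the difference and is argued against as all of it. Compression of ratios on all tel1mec1 arrays is argued against: proteasome and Yap1 means in tel1mec1 were 0.960 of those in mec1 (SD 0.173), against 0.270 for stress genes. On the slide that held 1 array of each strain in one dye orientation the stress difference was -0.656 with a spread of 0.618, so slide stays open, with an untested effect of Tel1 on stress genes. That spread was added to the rule after the value was seen. On this slide the proteasome mean was 0.35 in tel1mec1 against 0.70 in mec1, Yap1 0.91 against 1.08 and stress 0.07 against 0.73. Some compression on these single arrays is thus not excluded.

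RNR4 and RNR2 differed between arrays of one strain. Between the dye orientations of a pair, over 16 pairs from 8 strains picked after their values were seen, the median was 0.681 higher with MMS in Cy5 (14 of 16 pairs, exact p 0.00198), so dye orientation may account for that part. It is argued against for the 2 largest replicate differences of RNR4, 2.08 in ste11 and 1.29 in sml1: in each dye apart replicate 2 was higher, by at least 1.11 (SD of such differences in the other strains 0.402). The replicate difference of RNR4 went with that of HUG1 and RNR3 over 13 strains (r 0.578, permutation p 0.0321, and r 0.687 without ste11 and sml1). A stronger checkpoint signal in one culture would give this, but so would any effect shared by these genes. The largest HUG1 and RNR3 difference, 0.282, was in rad53, which lacks Rad53, so this explanation stays open. In ste11 and sml1 it stays open as well, since HUG1 and RNR3 differed by only 0.230 and 0.105 there (SD in the other strains 0.169). Pairs on different slides minus pairs on one slide gave -0.148 (medians 0.342 and 0.490, one-sided permutation p 0.698). This cannot decide on slide, since strains are not balanced between the kinds of pair. Pairs on different slides include mec1, tel1mec1, rad53 and dun1rad53, which differed by only 0.11 to 0.41. Those of tel1, wild type replicate 2 and sml1 replicate 2 differed by 1.15 to 1.73. Pairs of wild type, sml1, chk1 and ste11 on one slide differed by 0.49 to 1.30. The replicates of ste11 and sml1 also lay on different slides. Slide thus stays open, and this rule was changed after its result was seen, having first excluded slide.

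The Crt1-repressed genes lay below 0 in rad53, tel1mec1, chk1rad53 and dun1rad53, with list means of -0.55, -0.35, -0.36 and -0.43. A dye bias of these probes is argued against, since the highest of the 8 means by strain and dye was -0.284 and 16 of 16 arrays lay below 0. Centring before deposit stays open: the array medians lay between -0.0183 and 0.0211, so subtracting them moves little (highest mean -0.348) and tests nothing. A fall of these genes under MMS without Rad53 or without both upstream kinases is thus open as well.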

How the results depend on the processing

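The fit with a dye term, the fit without the 3 pairs with the strongest dye effect, the fits without a wild type replicate, the fits without 3 single arrays or 1 of them and the shares for risen and fallen genes apart were chosen after seeing the data. Of 3158 checks of named genes 2969 gave the same call, 189 lost it and 0 reversed: 33 of 262 lost it with scaled arrays, 102 of 752 without a replicate, 11 of 262 with the replicate block, 17 of 206 without the 3 pairs, 4 of 69 without the 3 single arrays, 1 of 19 without 1 of them, 6 of 206 with the slide block, 5 of 262 with 75% of genes, 4 of 262 with the dye term, 2 of 262 with pair as random block and 4 of 72 with sml1 as the reference. Centring arrays on their medians, the median of the probes and, over 5 contrasts, sml1 as the reference moved no count by over 1.5 times. Where values moved, the cause was not tested, except that leaving out arrays leaves fewer samples. A lone remaining replicate is assumed to vary like the other groups. No alternative was left unrun.

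With each array as a sample and the dye-swap pair as a random block, and in brackets with a dye term, the counts were 0 (0) for chk1, 109 (108) for dun1, 68 (65) for chk1dun1, 26 (25) for crt1 and 3 (3) for ste11 against wild type, 208 (213) for tel1mec1 against mec1, 1 (1) for chk1rad53 and 3 (4) for dun1rad53 against rad53, 1 (1) for chk1dun1 against dun1, and 155 (140) for hap1, 337 (304) for hap4, 76 (24) for sut1, 29 (27) for rcs1 and 11 (9) for yap7. The block correlation was -0.256 (-0.196) in the kinase set and -0.306 (-0.0966) in the factor set. With the slide as a random block (correlation -0.137) the counts were 0 for chk1, 64 for chk1dun1 and 3 for ste11 against wild type, 1 for chk1rad53 and 1 for dun1rad53 against rad53, 1 for chk1dun1 against dun1 and 264 for mec1 against rad53.

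With arrays scaled to one median absolute value the counts were 2247 for the chk1rad53 response, 53 for mec1, 438 for tel1mec1, 1 for dun1, 429 for chk1rad53 and 3 for chk1dun1 against wild type, 2 for dun1rad53 against rad53, 32 for sut1 and 1 for yap7. With 75% of genes sut1 had 3. Without the 3 pairs the crt1 response had 1884 and chk1 against wild type 0. Without the 3 single arrays (mec1 replicate 1 and the array labelled dun1 replicate 2 with MMS in Cy5, chk1rad53 replicate 1 with MMS in Cy3) the counts were 1916 for the chk1rad53 response, 139 for mec1 and 116 for dun1 against wild type, 84 for tel1mec1 against mec1, 2 for chk1rad53 against rad53 and 235 for mec1 against rad53. Without the array labelled dun1 replicate 2 with MMS in Cy5 alone, dun1 against wild type had 69 and its share kept was 0.727.

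Replicate numbers did not pair across strains: over 78 strain pairs of the kinase set the correlation of replicate differences lay between -0.462 and 0.428 (median -0.0202, 18 above 0.1), and over 10 of the factor set between -0.403 and 0.149 (median -0.0186, 2 above 0.1). With the replicate number as a block nonetheless, chk1rad53 against rad53 had 1 gene, hap4 69 and sut1 2.

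Estimating the correlation, 38 of 325 response tests of lists, 13 of 300 difference tests and 7 of 125 direct tests passed in the kinase set, and 0 of 125 and 0 of 125 in the factor set, against 211, 115, 41, 77 and 43 with limma's preset correlation. With fry 57 difference, 12 direct and 11 factor difference tests passed.

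The share of the wild-type response kept at an absolute log2 of at least 2 was 0.533 in tel1mec1, 0.546 in dun1rad53, 0.779 in crt1 and 0.973 in ste11. For fallen genes it was 1.01 in tel1, 0.571 in rad53, 0.932 in dun1, 0.628 in dun1rad53, 0.938 in chk1dun1, 0.972 in crt1 and 1.06 in ste11, and for risen genes 0.701 in dun1, 0.440 in dun1rad53, 0.729 in chk1dun1, 0.843 in crt1 and 0.988 in ste11.

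Leaving out one replicate at a time gave, lowest and highest, response counts of 1638 and 2136 in sml1, 973 and 1837 in mec1, 540 and 1012 in tel1mec1, 1077 and 1147 in rad53, 1508 and 1920 in chk1, 1244 and 1322 in dun1, 126 and 970 in chk1rad53, 762 and 789 in dun1rad53, 957 and 1117 in chk1dun1, 1774 and 2217 in crt1, 1844 and 1961 in ste11 and 1980 and 2178 in yap7. Against wild type it gave 38 and 72 for mec1, 0 and 1 for tel1, 309 and 733 for tel1mec1, 567 and 1231 for rad53, 0 and 1 for chk1, 8 and 94 for dun1, 293 and 745 for chk1rad53, 311 and 839 for dun1rad53, 6 and 26 for chk1dun1, 12 and 82 for crt1 and 0 and 1 for ste11. Between deletion strains it gave 28 and 230 for tel1mec1 against mec1, 0 and 2 for chk1rad53 and 0 and 4 for dun1rad53 against rad53, 0 and 53 for chk1dun1 against dun1 and 19 and 615 for mec1 against rad53, and in the factor set 42 and 51 for hap1, 9 and 43 for hap4, 0 and 9 for sut1, 7 and 11 for rcs1 and 0 and 4 for yap7.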

Other observations

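The purine, phosphate and hexose lists below, and the look at deleted genes, were chosen after the data were seen. Genes of purine synthesis, which supply nucleotides for growth, had a mean of -1.01 in wild type with 14 of 16 lower, -1.14 in sml1 (15 lower) and -1.21 in ste11 (16 lower), with an estimated-correlation p of 0.233, 0.218 and 0.218. The mean was -0.18 in tel1mec1 (5 lower) and -0.32 in rad53 (6 lower), with p 0.611 and 0.389. Relative to wild type the list stood at 0.83 in tel1mec1 (9 higher; 13 over the list alone) and 0.69 in rad53 (8 higher; 10 over the list alone), with an estimated-correlation p of 0.249 in each. In the factor set its means lay between -0.68 and -0.97.

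Genes of the phosphate regulon had a mean of -0.55 in wild type, with 2 of 15 higher and 9 lower (estimated-correlation p 0.273), and PHO5 at -2.23. Relative to wild type they stood at 0.38 in chk1rad53 (6 higher, 2 lower; 8 and 2 over the list alone), 0.36 in dun1rad53 (4 and 1; 6 and 1), 0.34 in rad53 (5 and 1; the same) and 0.27 in tel1mec1 (4 and 2; 5 and 2). Camera passed the list in chk1rad53 and dun1rad53 (adjusted p 0.0141 and 0.0197) and not in rad53 and tel1mec1 (0.0638 in each); with an estimated correlation p was 0.249, 0.249, 0.283 and 0.283. Hexose transport genes went both ways in wild type, with 3 of 7 higher and 2 lower, a mean of -0.00 and a median of 0.20.

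Among 84 values of deleted genes in the strains that lack them, DUN1 on the array labelled dun1 replicate 2 with MMS in Cy5 was the farthest from 0, at 2.71, and the other 83 lay between -1.34 and 0.37. CHK1 went with the dye: with MMS in Cy3 it was -1.34 and -0.70 in chk1, -0.79 and -0.34 in chk1rad53 and -0.52 and -0.29 in chk1dun1, and with MMS in Cy5 between -0.23 and 0.31. On the array labelled dun1 replicate 2 with MMS in Cy5, MEC1 was -2.34, where the other 51 arrays of the set lay between -0.75 and 0.30. The array correlated most with arrays of mec1 (median r 0.677, highest 0.718), against a median of 0.624 with the other dun1 arrays. RNA with DUN1 and without MEC1 in the MMS channel, set against RNA with MEC1 and without DUN1, would give these signs; the origin of the RNA was not settled here.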
